A study of Mus musculus with 8 samples.

How the data were processed

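The samples were cultures of MC3T3-E1 subclone 14, a mouse calvarial cell line of the osteoblast lineage, treated for 24 h with 10 µM Yoda1, a small-molecule agonist of the mechanically gated cation channel PIEZO1, or with DMSO, its solvent. The labels name 8 samples, 4 per group, and state that 1 library of each group (DMSO replicate 3 and Yoda1 replicate 1) was left out of the submitters' final analysis for batch variation, which leaves 3 per group. Total RNA was extracted and libraries were made with a TruSeq RNA kit, per the labels' protocols. The series' design text describes another cell type and was not followed where it differs from the sample labels. It calls its replicates biological, but nothing in the sample labels says that those of MC3T3-E1 came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

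One table was used, holding a single comparison by the authors with 1 value per gene and no values per library. Salmon, DESeq2 and build GRCm39 are named without versions, per the submitters' processing notes. The column names of the table are those of a DESeq2 result, per the file headers. The mean normalized count is a signal that the authors averaged over the libraries of their fit. The log2 fold change and its standard error are the authors' values. The direction of the fold change, Yoda1 over DMSO, rests on the name of the deposited table and was not checked against libraries. The Wald statistic is a score that equals the fold change divided by its standard error, per the file headers and a check of the values. The unadjusted p-value equals the two-sided normal tail of that score, and the adjusted p-value equals the Benjamini-Hochberg adjustment over the rows that the authors gave one. Each row also carries the authors' class, which a check of all rows reproduced with 0 exceptions as an adjusted p under 0.05 and an absolute log2 fold change above 0.5. Which libraries entered the authors' fit, its design formula and its filters are not given in the sources used here, apart from the group size in the table's name and the exclusions in the labels.

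Depth per library was not analysed here. The mean normalized counts summed to 19849773 over 20972 rows, and precision followed the level: the median standard error of the deposited log2 fold change was 0.116 for tested genes with a mean of 100 or more and 0.754 for those below. An adjusted p was given for 14653 rows, which are called tested genes, and the lowest mean among them was 1.92. Of the 6319 other rows, 8 had no unadjusted p either. The 21 symbols that occur more than once were kept as separate rows in counts, and the row with the higher mean was used for list members and named genes. Ensembl IDs stood in place of symbols in 4447 rows.

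The design written before the data were examined foresaw a count test or limma on values per library, and the authors' own comparison where no such values were held. That last case applied, so the main result is the authors' comparison at an adjusted p under 0.05 with no fold threshold. The 37 gene lists and the rule for named genes were also written before the data were examined. The list test was cameraPR of limma 3.58.1 in R 4.3.3 on the authors' Wald statistics, two-sided, with a preset inter-gene correlation of 0.01, lists of at least 3 tested members, and Benjamini-Hochberg adjustment over the 37 lists. It took the place of camera on values per library. Counts of members of these lists are given over all tested genes and adjusted over the list alone. A correlation estimated from the libraries could not be had.

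The rule for named genes took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean at or above the median of the tested genes, 423, leaving out Gm and Rik names and IDs with no symbol. Its further condition, that the libraries of the 2 groups do not overlap, could not be applied. The rule also took 19 genes whatever their result and up to 4 members with the smallest adjusted p in each list described. Of the 19 genes, Bmp2 and Tnfsf11 had no row under these symbols in the table used, so they were not analysed here. Where 5 or fewer members of a list changed in one direction, those outside the rule are named as well and were chosen after their values were seen. Some genes that these rules select are not reported here. Ratios and their 95% intervals were computed from the deposited log2 fold changes and standard errors with the normal distribution.

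Alternatives planned before the data were examined were no filter, a filter at 5 times the lowest tested mean, a trimmed-mean centring of the fold changes, and fold thresholds of 0.5 and 1. Alternatives chosen after seeing the data were median centring, centring to equal summed counts of the 2 groups, a t distribution with 4 degrees of freedom in place of the normal one, a test against an absolute log2 fold change of 0.5, removal of a trend with transcript length and GC content, genes with plain symbols only, ranks of the statistics, and a preset correlation of 0.05. The trend was a robust quadratic fit in statsmodels 0.14.6 of the fold change on log2 transcript length and GC content over 9076 genes with a mean of at least 100 that belong to no list. Lengths and GC contents were those of the longest protein-coding transcript of each symbol in GENCODE M21, which is on another build than the authors used, so no coordinates are given. They were found for 12003 tested genes, 81.9% of the total and 95.1% of those with plain symbols. Every fixed list except nuclear-retained RNA and replication histones, which had none, had a length for at least 80% of its tested members. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

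The steps were tested on simulated data for the comparison of Yoda1 with DMSO, drawn from the real standard errors of 14653 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale and the cholesterol list lowered. These 2 sets of changed genes were picked among genes with a mean of at least 100, a transcript length and no list membership. Of the changes by 1, 98% were recovered, and of those by 2, 100%. Recovery below a mean of 100, where the median standard error was 0.754, was not simulated. Of the calls, 5.26% were unchanged genes, and 0 of the 36 other lists were called. With a planted trend on transcript length, 78.6% of the calls were genes without a planted change and 2 of the 36 other lists were called. Removing the fitted trend over 12003 genes brought these to 4.82% of the calls and 0 of 34 lists. The planted trend was linear in log2 transcript length, a form that the fit contains, so its removal was assured. A trend of another form or a larger share of changed genes was not simulated. The simulated noise was normal and independent between genes, as the gene test assumes. These rates therefore do not cover correlation between genes or error in the standard errors, and they do not give the error rate of the real calls.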

Results

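The labels describe RNA-seq of MC3T3-E1 cells, an osteoblastic line from mouse calvaria that can lay down and mineralise a collagen matrix. Cells received 10 µM Yoda1, which opens the calcium-permeable channel PIEZO1, or the solvent DMSO for 24 h. Each group had 4 samples, of which the labels keep 3. The series title places the comparison in a question about PIEZO1, the BMP antagonist GREM1 and bone formation. All gene values below are from the authors' deposited table, which gives a mean normalized count over both groups and a log2 fold change with its standard error for each gene. Depth per library was not analysed here, and the means summed to 19849773 normalized counts.

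The Yoda1 and DMSO cultures differed in many genes, and genes of extracellular matrix proteins stood among both the largest falls (Ibsp and Tnc) and the largest rises (Dmp1 and Spp1). Tnfrsf19, a TNF receptor family member, was 52.4-fold lower with Yoda1 (95% interval 38.2 to 71.8) and Ibsp, which encodes bone sialoprotein, was 29.9-fold lower (24.8 to 36.1) in the authors' deposited table. The keratin gene Krt14 was 29.6-fold lower (22.8 to 38.3), and Tnc, which encodes the matrix glycoprotein tenascin C, was 12.8-fold lower (11.6 to 14.2) in the authors' deposited table. The other 4 of the 8 largest falls in the authors' deposited table were Mest (log2 fold change -3.90, standard error 0.11), the retrotransposon-derived gene Rtl3 (-3.82, 0.17), the IGFBP protease gene Pappa2 (-3.64, 0.29) and Thsd4 (-3.36, 0.56). On the other side, the junctional adhesion gene Jam2 was 33.4-fold higher (24.8 to 45.0) and the semaphorin gene Sema7a 30.3-fold higher (24.9 to 36.9) in the authors' deposited table. The remaining 6 of the 8 largest rises in the authors' deposited table were Hmga1, an architectural chromatin protein (log2 fold change 3.77, standard error 0.08), Tspan11 (3.67, 0.09), Dmp1 (3.43, 0.10), St3gal1 (3.19, 0.10), the IL-33 receptor gene Il1rl1 (3.02, 0.08) and Spp1 (2.89, 0.08). Thsd4 had the largest adjusted p of these 16 genes in the authors' deposited table, 1.76e-08.

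By the adjusted p of the DESeq2 test in the authors' deposited table, 6518 of 14653 tested genes (44.5%) passed the threshold, 3285 higher and 3233 lower with Yoda1. The authors' class, which also asks for an absolute log2 fold change above 0.5, held 2023 higher and 1954 lower genes. With the fold changes centred so that the summed counts of the 2 groups were equal, which subtracts -0.11 on the log2 scale and so raises every value, the split became 4138 higher and 2500 lower. The number of genes fell to 2990 with a t distribution of 4 degrees of freedom and to 1393 in a test against an absolute log2 fold change of 0.5.

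Collagen genes fell together. Of 20 tested collagen genes, 18 were lower with Yoda1 and 0 were higher, with the same counts adjusted over the list alone, and the median log2 fold change was -1.08 (camera adjusted p = 8.13e-27). Col1a1, the main collagen of bone, was 2.73-fold lower (95% interval 2.41 to 3.11) at a mean of 171434 normalized counts, and the fibrillar collagen gene Col11a1 was 7.19-fold lower (6.0 to 8.60) in the authors' deposited table. Col5a1 was 3.62-fold lower (3.24 to 4.04), and Col6a2 and Col6a1, which encode chains of the beaded-filament collagen VI, were 2.33-fold (2.15 to 2.52) and 2.16-fold lower (2.00 to 2.34) in the authors' deposited table. Among 35 genes of collagen processing and other matrix components, 24 were lower and 6 higher, both also when adjusted over the list alone (camera adjusted p = 2.37e-18). Besides Tnc, the small leucine-rich proteoglycan genes Fmod and Aspn (log2 fold change -1.92 and -2.77, standard errors 0.07 and 0.11) and the fibrillin gene Fbn2 (-3.0, 0.14) fell in the authors' deposited table. The list of matrix proteases and their inhibitors had 14 lower and 4 higher members of 22, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.0141, 0.0779 with a preset correlation of 0.05, range over the alternatives 0.00276 to 0.0779). Timp1, Plaur and Mmp10 were among its higher members. The metalloprotease inhibitor Timp3 (log2 fold change -1.39, standard error 0.08), the aggrecanase Adamts4 (-2.14, 0.14) and the plasminogen activator Plat (-1.77, 0.12) fell in the authors' deposited table.

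The osteoblast differentiation list was lower as a whole but its members did not all move one way. Of 29 tested members, 17 were lower and 3 higher, or 18 and 3 adjusted over the list alone (median log2 fold change -0.95, camera adjusted p = 1.14e-14). The transcription factor genes Runx2 and Sp7 were 1.87-fold (95% interval 1.67 to 2.08) and 1.44-fold lower (1.29 to 1.6) in the authors' deposited table. Alpl, the tissue-nonspecific alkaline phosphatase, was 60.3-fold lower with a wide interval (24.4 to 149) at a mean of 47.3 normalized counts in the authors' deposited table. Postn, which encodes periostin, was 5.96-fold lower (5.36 to 6.62) and Tnn, which encodes tenascin W, 4.43-fold lower (4.00 to 4.90) in the authors' deposited table. The osteocalcin gene Bglap had a mean of only 4.70 normalized counts in the authors' deposited table, with a log2 fold change of -1.85 (standard error 1.08, DESeq2 adjusted p = 0.158), so a difference was not detectable at this level. The 3 higher members were Spp1, Enpp1 and Twist1. Spp1, which encodes osteopontin, was 7.44-fold higher (6.70 to 8.26) at a mean of 153543 normalized counts in the authors' deposited table.

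Lists of neighbouring skeletal cell types gave smaller counts. Of 11 tested chondrocyte markers, 5 were lower (Hapln1, Col2a1, Matn3, Sox6 and Sox9) and 0 higher, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0152). In the authors' deposited table, Hapln1, the cartilage link protein, had a log2 fold change of -2.66 (standard error 0.26), the cartilage collagen gene Col2a1 -0.88 (0.10), Matn3 -4.18 (0.60) and Sox6 -2.16 (0.31). Of 7 tested osteocyte markers, Dmp1 and Cd44 were higher and Irx5 was lower, also when adjusted over the list alone. Dmp1, a matrix phosphoprotein gene of osteocytes, was 10.8-fold higher (95% interval 9.42 to 12.4), Cd44 1.93-fold higher (1.79 to 2.08) and Irx5 3.55-fold lower (3.02 to 4.17) in the authors' deposited table. The call of the osteocyte list (camera adjusted p = 0.0107) rested on Dmp1: without that gene the adjusted p over the added lists was 0.953, and with ranks in place of the statistics the adjusted p was 0.723 (range over the alternatives 0.00801 to 0.723).

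**Figure D1:**
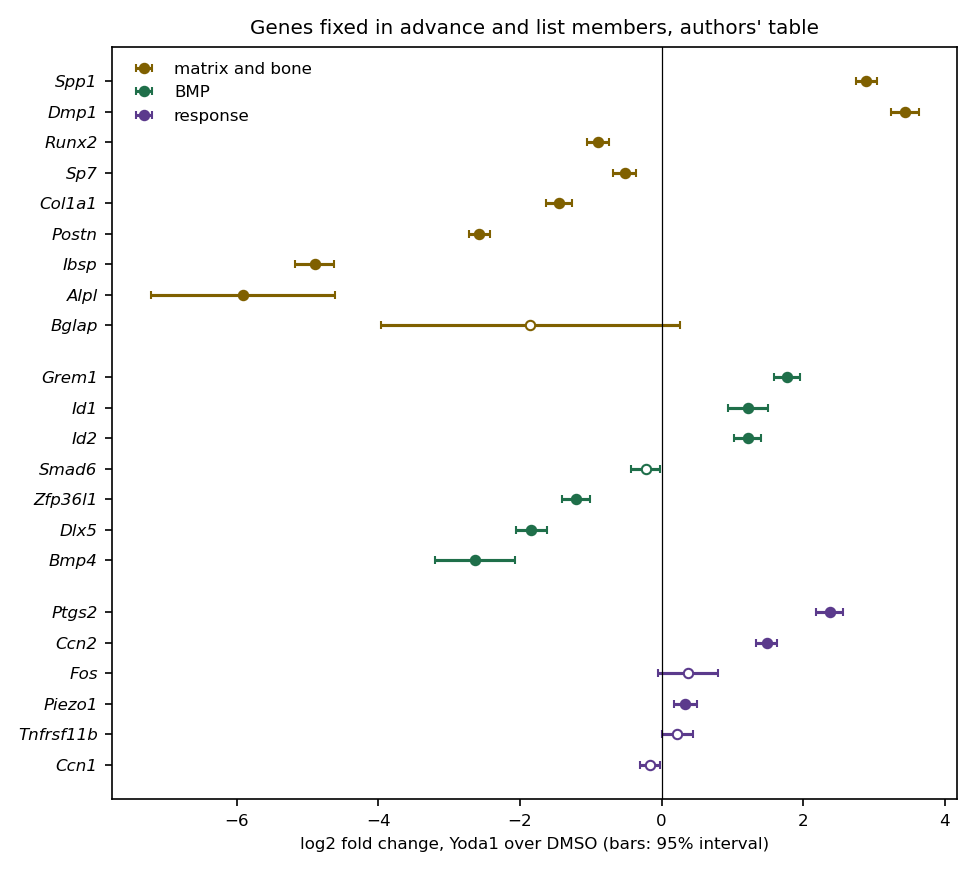
Log2 fold change of Yoda1 over DMSO for selected genes of bone and matrix, BMP signalling and the response to mechanical or calcium stimuli, from the authors' deposited table. Bars are 95% intervals, filled points have an adjusted p under 0.05 and open points do not; Spp1 and Dmp1 lie to the right of 0 at 2.89 and 3.43, while Ibsp and Alpl lie at -4.90 and -5.91.

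The BMP pathway moved in both directions. The BMP antagonist gene Grem1 was 3.42-fold higher (95% interval 3.01 to 3.89) and the ligand gene Bmp4 was 6.21-fold lower (4.18 to 9.21) in the authors' deposited table. The antagonist genes Fstl1 (log2 fold change -0.53, standard error 0.06) and Fst (-0.89, 0.10) fell in the authors' deposited table. Of 18 tested antagonists, 5 were higher (Grem1, Bmper, Nbl1, Tmem53 and Twsg1) and 7 lower, with the same counts adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.717). Of 16 ligands, receptors and SMADs, 3 were higher (Tgfbr3, Acvr1 and Rgmb) and 5 lower (Bmp4, Bmp1, Smad9, Bmpr2 and Gdf6), or 4 and 5 adjusted over the list alone (camera adjusted p = 0.717). The call of Smad9 was lost with a t distribution (adjusted p = 0.0808, range over the alternatives 0.00101 to 1). Of 20 BMP target genes, 6 were higher and 7 lower, or 6 and 9 adjusted over the list alone, with no call (camera adjusted p = 0.809). Among them, Id1 and Id2, inhibitors of bHLH factors, were 2.33-fold (1.92 to 2.83) and 2.32-fold higher (2.04 to 2.64) in the authors' deposited table, while the homeobox gene Dlx5 was 3.58-fold lower (3.09 to 4.16) and Zfp36l1 2.31-fold lower (2.02 to 2.65). The inhibitory SMAD gene Smad6 had a log2 fold change of -0.23 (standard error 0.10, DESeq2 adjusted p = 0.0652) in the authors' deposited table. Once the trend with transcript length and GC content was removed, Smad6 stood at -0.37 with an adjusted p of 0.00119 (range over the alternatives 0.00119 to 1).

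TGF-beta target genes also parted, with 11 of 21 higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.828). Ccn2, a matricellular protein gene, was 2.80-fold higher (95% interval 2.53 to 3.11), while the ligand gene Tgfb3 had a log2 fold change of -1.41 (standard error 0.09) in the authors' deposited table. Of 26 Wnt pathway genes, 6 were higher and 13 lower, also adjusted over the list alone, without a call of the list (camera adjusted p = 0.337). The R-spondin receptor gene Lgr6 was 5.40-fold higher (4.80 to 6.08) in the authors' deposited table, and Rspo2 (log2 fold change -1.99, standard error 0.15), Sfrp2 (-0.88, 0.09) and Tcf7l2 (-1.37, 0.16) fell.

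Genes of the calcium and immediate-early response were higher at 24 h. Of 33 tested members, 17 were higher and 4 lower (Egr2, Nfatc1, Nfatc2 and Myc), or 18 and 4 adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 1.98e-08). The prostaglandin synthase gene Ptgs2 was 5.19-fold higher (95% interval 4.55 to 5.94), the MAP kinase phosphatase genes Dusp1 and Dusp4 were 7.07-fold (5.66 to 8.85) and 14.9-fold higher (10.9 to 20.3), and Ier3 was 3.08-fold higher (2.67 to 3.55) in the authors' deposited table. Fos itself had a log2 fold change of 0.37 (standard error 0.22, DESeq2 adjusted p = 0.153) in the authors' deposited table. Of 23 mechanosensitive and calcium channel genes, 5 were higher (Itpr3, P2rx4, Tmem63a, Piezo1 and Pkd1) and 6 lower, also adjusted over the list alone. That list was not called, and its test pointed down (camera adjusted p = 0.677, mean log2 fold change -0.12) although its median was 0.09. Piezo1 was 1.26-fold higher (1.13 to 1.41, DESeq2 adjusted p = 0.000214) in the authors' deposited table, with an adjusted p of 0.0637 against a t distribution (range over the alternatives 6.68e-07 to 1). The pannexin gene Panx3 was 15.4-fold lower (10.6 to 22.4) in the authors' deposited table, where the gap junction gene Gja1 (log2 fold change -0.57, standard error 0.08) and the calcium sensor gene Stim2 (-0.81, 0.10) fell and the IP3 receptor gene Itpr3 (0.49, 0.06) rose.

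Targets of the mechanically regulated coactivators YAP and TAZ were split, with 9 of 23 higher and 7 lower, or 9 and 8 adjusted over the list alone. The list was called higher (camera adjusted p = 0.0284), but not with ranks (0.460) or a preset correlation of 0.05 (0.120; range over the alternatives 0.00716 to 0.460). In the authors' deposited table, the receptor kinase gene Axl was 2.29-fold higher (95% interval 2.11 to 2.49) and the ectonucleotidase gene Nt5e 7.60-fold higher (5.61 to 10.3), the coagulation factor gene F3 was 1.90-fold lower (1.70 to 2.13), and Ccn1 had a log2 fold change of -0.16 (standard error 0.07, DESeq2 adjusted p = 0.0647). With the length and GC trend removed, Ccn1 stood at -0.27 with an adjusted p of 0.000648 (range over the alternatives 0.000648 to 1). Of 25 contractile and cytoskeletal genes, 12 were lower and 3 higher (Fhl2, Flna and Myl9), or 13 and 3 adjusted over the list alone (camera adjusted p = 0.00539). The smooth muscle actin gene Acta2 was 3.13-fold lower (2.80 to 3.51), Mylk 2.54-fold lower (2.22 to 2.91) and Csrp1 1.65-fold lower (1.5 to 1.81), and Fhl2 was 3.25-fold higher (2.88 to 3.67) in the authors' deposited table.

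Signals from osteoblasts to osteoclasts and inflammatory genes changed singly. Of 20 genes that couple the cells, 7 were higher and 3 lower (Efnb2, Lgr4 and Cxcl12), or 7 and 4 adjusted over the list alone (camera adjusted p = 0.107, but 0.0420 with no filter and 0.0439 with the stricter filter; range over the alternatives 0.0420 to 0.50). The prostaglandin E synthase gene Ptges (log2 fold change 1.15, standard error 0.12) and the CSF1 receptor ligand gene Il34 (1.97, 0.20) rose and Efnb2 (-1.28, 0.14) fell, while Tnfrsf11b, which encodes osteoprotegerin, stood at 0.22 (0.11, DESeq2 adjusted p = 0.0948) in the authors' deposited table. The adjusted p of Tnfrsf11b was 0.0159 with the length and GC trend removed and 0.00905 with equal summed counts (range over the alternatives 0.00905 to 1). Of 19 NF-kappaB genes, 4 were higher (Il1rl1, Ptgs2, Tnfaip2 and Relb) and 4 lower (Vcam1, Mmp13, Mmp9 and Nfkbia), also adjusted over the list alone. The test of this list pointed up (camera adjusted p = 0.403) while its median and mean log2 fold changes were -0.40 and -0.48. The adhesion gene Vcam1 (-1.14, standard error 0.09) and the collagenase gene Mmp13 (-1.06, 0.11) were lower on the log2 scale in the authors' deposited table. Of 21 interferon response genes, 1 was higher (Ifit1) and 4 were lower, among them Rigi, Ifi44 and Gbp2, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.490). Rigi had a log2 fold change of -0.98 (standard error 0.17), Ifi44 -1.52 (0.31) and Ifit1 1.28 (0.28) in the authors' deposited table. The call of Ifit1 was lost with a t distribution (adjusted p = 0.0503, range over the alternatives 4.28e-06 to 0.0560), and in the test against a fold of 0.5 that of Rigi was lost too (0.0529, range 7.33e-08 to 0.0529).

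Mitotic genes were lower, while the list of DNA replication genes missed the threshold. Of 26 genes of G2 and mitosis, 17 were lower and 2 higher (Cdk1 and Aurkb), or 18 and 2 adjusted over the list alone (camera adjusted p = 9.63e-06). The mitotic kinase gene Plk1 and the kinetochore genes Nuf2, Cenpf and Cenpe had log2 fold changes of -0.99, -1.01, -0.96 and -0.86, with standard errors of 0.08, 0.09, 0.10 and 0.09 in the authors' deposited table. Of 28 S phase genes, 15 were higher and 1 lower (Rrm1), also adjusted over the list alone. The S phase list missed the threshold (camera adjusted p = 0.0604) and passed it with ranks (0.00945), with no filter (0.0187) and with equal summed counts (0.0183; range over the alternatives 0.00945 to 0.219). Fen1, Rfc4, Pcna and Mcm3, which act at the replication fork, had log2 fold changes of 0.64, 0.99, 0.34 and 0.35 in the authors' deposited table, with standard errors of 0.08, 0.16, 0.06 and 0.07.

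The stress lists separated into 2 that rose, 1 that fell and 2 with no call. The integrated stress response list, which holds amino acid synthesis and tRNA charging genes, had 17 higher and 2 lower members (Aldh1l2 and Nars1) of 28, also adjusted over the list alone (camera adjusted p = 0.000470). In the authors' deposited table, the serine synthesis gene Psph was 3.04-fold higher (95% interval 2.65 to 3.48), Ddit4 2.91-fold (2.41 to 3.52), the asparagine synthetase gene Asns 1.55-fold (1.41 to 1.70) and Gars1 1.58-fold higher (1.43 to 1.74). Of 19 NRF2 target and metallothionein genes, 13 were higher and 3 lower (Gstm1, Gsta4 and Osgin1), also adjusted over the list alone (camera adjusted p = 4.22e-05). The thioredoxin reductase gene Txnrd1 was 2.76-fold (2.54 to 3.00), the quinone reductase gene Nqo1 3.06-fold (2.77 to 3.39), Taldo1 2.49-fold (2.19 to 2.82) and the ferritin gene Ftl1 1.74-fold higher (1.55 to 1.95) in the authors' deposited table. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 13 were lower and 4 higher (Atf6, Sdf2l1, Hyou1 and Derl1), also adjusted over the list alone (camera adjusted p = 0.00555). The chaperone genes Pdia4, Calr and Hsp90b1 were 1.89-fold (1.71 to 2.10), 2.02-fold (1.80 to 2.26) and 1.86-fold lower (1.65 to 2.10), and Atf6 was 1.54-fold higher (1.39 to 1.70) in the authors' deposited table. Heat shock genes (7 higher and 5 lower of 16, camera adjusted p = 0.337) and p53 targets (7 higher and 7 lower of 20, camera adjusted p = 0.855) were not called, and their counts were the same adjusted over the list alone. The 5 lower heat shock genes were Bag3, Hsp90aa1, Hsp90ab1, Dnajb1 and Dnajb4. The heat shock genes Hspa4l, Hsph1, Hspa1b and Bag3 had log2 fold changes of 2.00, 0.74, 0.73 and -0.61 (standard errors 0.13, 0.09, 0.10 and 0.10), and the p53 targets Sesn1, Bax, Bbc3 and Phlda3 stood at -0.98, 0.79, -1.34 and 0.69 (0.11, 0.10, 0.18 and 0.09) in the authors' deposited table. With the length and GC trend removed, Ftl1, Bax and Phlda3 stayed past the threshold at smaller log2 fold changes of 0.46, 0.43 and 0.40, against 0.80, 0.79 and 0.69 before.

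The sterol synthesis list fell and the list of hypoxia and glycolysis genes rose. Of 23 cholesterol biosynthesis genes, 21 were lower and 0 higher, also adjusted over the list alone (median log2 fold change -0.68, camera adjusted p = 2.32e-11). Hmgcs1, which makes HMG-CoA, was 2.75-fold lower (95% interval 2.48 to 3.05), and Acat2, Pmvk and Idi1 were 1.85-fold (1.67 to 2.05), 2.49-fold (2.13 to 2.91) and 2.21-fold lower (1.90 to 2.57) in the authors' deposited table. Of 19 lipid synthesis genes, 10 were lower and 3 higher (Acsl4, Agpat2 and Dgat2), also adjusted over the list alone (camera adjusted p = 0.00126). The desaturase genes Scd2 and Scd1, the elongase gene Elovl6 and Acsl3 had log2 fold changes of -1.35, -0.94, -0.88 and -1.45 in the authors' deposited table (standard errors 0.07, 0.08, 0.09 and 0.17). Of 27 hypoxia and glycolysis genes, 15 were higher and 5 lower (Ndrg1, Gapdh, P4ha1, Pfkfb4 and Pfkfb3), also adjusted over the list alone (camera adjusted p = 0.00158). Vegfa, which encodes an angiogenic growth factor, was 2.93-fold higher (2.62 to 3.28), and the glycolytic genes Aldoa and Ldha were 2.36-fold (2.06 to 2.71) and 1.66-fold higher (1.53 to 1.81) in the authors' deposited table. Of 25 lysosome and autophagy genes, 10 were higher and 7 lower, also adjusted over the list alone, without a call (camera adjusted p = 0.220). The lysosomal genes Ctsb, Npc2, Ctsa and Gla had log2 fold changes of 1.08, 0.73, 0.56 and 1.08 in the authors' deposited table (standard errors 0.11, 0.09, 0.07 and 0.15).

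**Figure D2:**
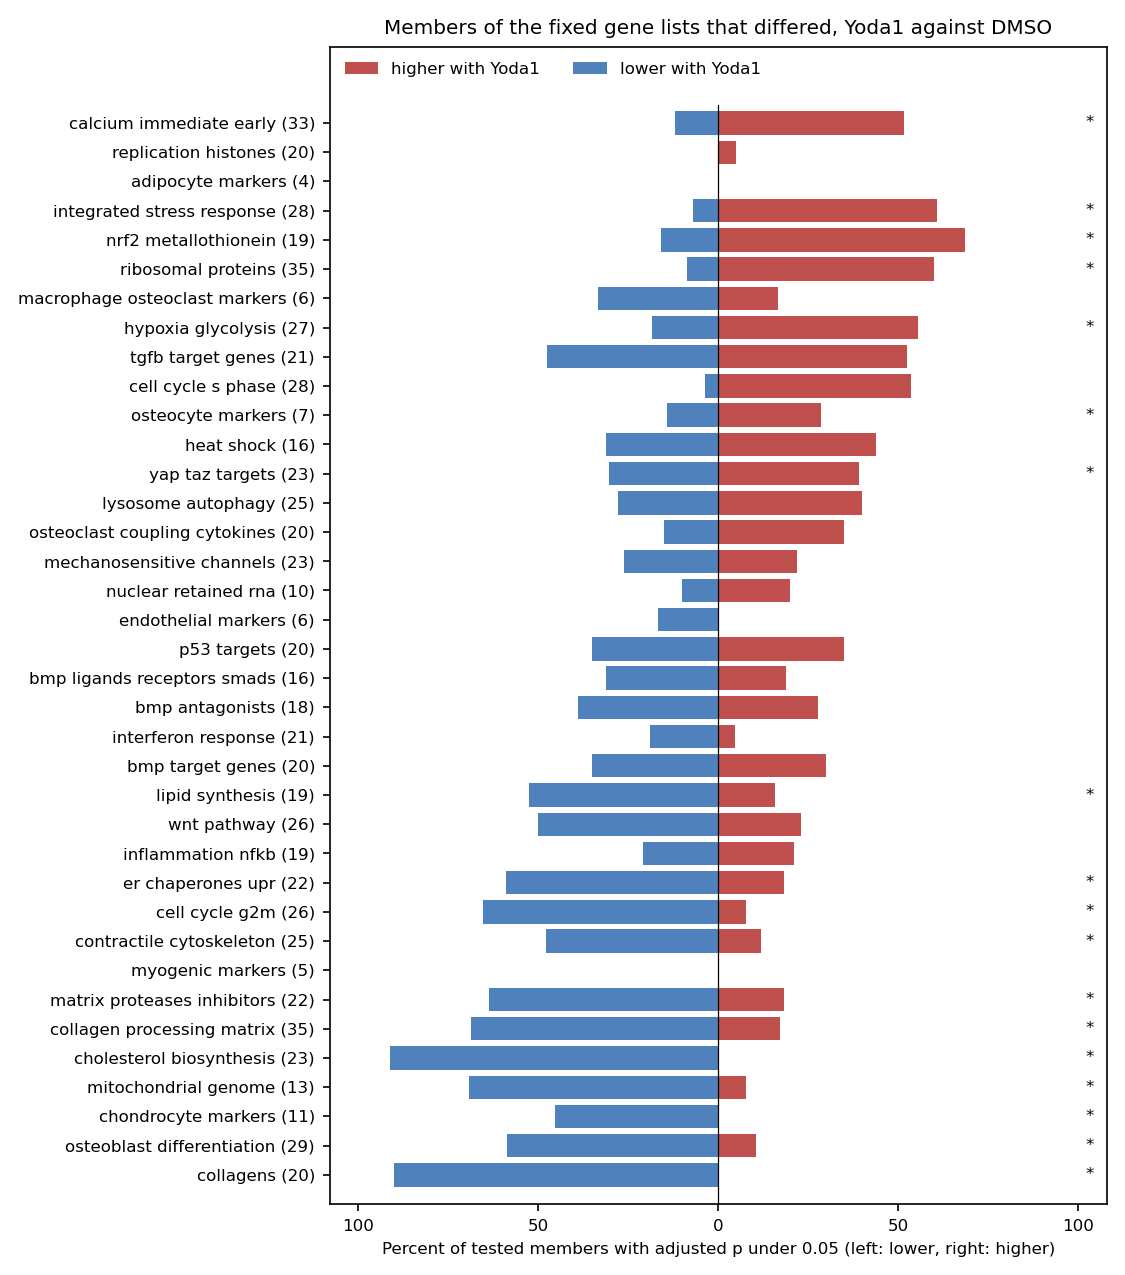
Share of the tested members of each fixed gene list with an adjusted p under 0.05, in percent of members, drawn to the right where higher with Yoda1 and to the left where lower; the number of tested members stands in brackets and an asterisk marks a camera adjusted p under 0.05. Lists are ordered by median log2 fold change, and collagens (0 higher and 18 lower of 20) stand at the bottom.

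Markers of other cell types gave few calls. None of 4 adipocyte markers (camera adjusted p = 0.717) or 5 myogenic markers (0.830) passed the DESeq2 threshold, and their counts stayed at 0 adjusted over the list alone. Of the 21 tested markers of these 2 cell types and of endothelial cells and macrophages, 9 had a mean under 10 normalized counts, so that all but very large differences in them were not detectable. Of 6 endothelial markers Flt1 was lower (camera adjusted p = 0.442, mean log2 fold change -0.23 with a median of 0.00), and of 6 macrophage and osteoclast markers Cd14 was higher and Lyz2 and Ctsk were lower (camera adjusted p = 0.383), in both lists also adjusted over the list alone. The VEGF receptor gene Flt1 had a log2 fold change of -1.38 (standard error 0.12), the lipopolysaccharide co-receptor gene Cd14 2.73 (0.14), Lyz2 -1.35 (0.23) and Ctsk -0.22 (0.08) in the authors' deposited table. With the length and GC trend removed, Ctsk stood at -0.34. Its call was lost with equal summed counts (adjusted p = 0.290) and with a t distribution (0.152; range over the alternatives 0.000252 to 1).

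Lists that can follow RNA quality or library composition also moved. Of 13 protein-coding mitochondrial genes, 9 were lower and mt-Co3 was higher, also adjusted over the list alone (camera adjusted p = 0.0338, 0.0973 with a preset correlation of 0.05, range over the alternatives 0.0102 to 0.0973). In the authors' deposited table, mt-Nd1, mt-Nd4 and mt-Cytb had log2 fold changes of -1.01, -0.73 and -0.86 (standard errors 0.10, 0.09 and 0.13), against 1.5 (0.17) for mt-Co3. Of 35 cytosolic ribosomal protein genes, 21 were higher and 3 lower, Rplp0 and Rps15 among the latter, also adjusted over the list alone (camera adjusted p = 0.000397). These genes share sequence with many processed pseudogenes, so their values are uncertain where reads could be assigned to either. Rps27a, Rps13 and Rps19 had log2 fold changes of 1.72, 1.19 and 1.31 in the authors' deposited table (standard errors 0.13, 0.11 and 0.14). With a trend of the fold change on transcript length and GC content removed, the adjusted p of the ribosomal protein list was 0.487 (range over the alternatives 1.18e-05 to 0.487). Of 10 nuclear-retained RNAs, Rn7sk and Rpph1 were higher and Snhg12 was lower (camera adjusted p = 0.917), and of 20 replication histone genes H1f2 was higher (camera adjusted p = 0.537), with the same counts adjusted over the list alone. All 3 higher calls, of Rn7sk (adjusted p = 0.0772, range over the alternatives 0.000163 to 0.690), Rpph1 (0.0976, range 0.00169 to 0.219) and H1f2 (0.0653, range 1.34e-05 to 1), were lost with a t distribution. The 18S ribosomal RNA gene Rn18s, chosen after its values were seen, held 1.75% of the summed means and had a log2 fold change of 0.63 (standard error 0.13) in the authors' deposited table.

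Across 9637 genes with a mean of at least 100, the deposited log2 fold change went down with transcript length (Spearman's rho = -0.20) and up with GC content (rho = 0.20). These are 2 descriptions across genes, which are not independent replicates. Genes in the shortest decile of transcript length had a median log2 fold change of 0.27, with 462 of 964 genes higher and 150 lower. Genes in the longest decile had a median of -0.13, with 180 of 964 higher and 358 lower. With the trend removed, 5851 of 12003 genes passed the threshold (2829 higher and 3022 lower), against 6077 of the same genes before (3067 higher and 3010 lower).

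**Figure D3:**
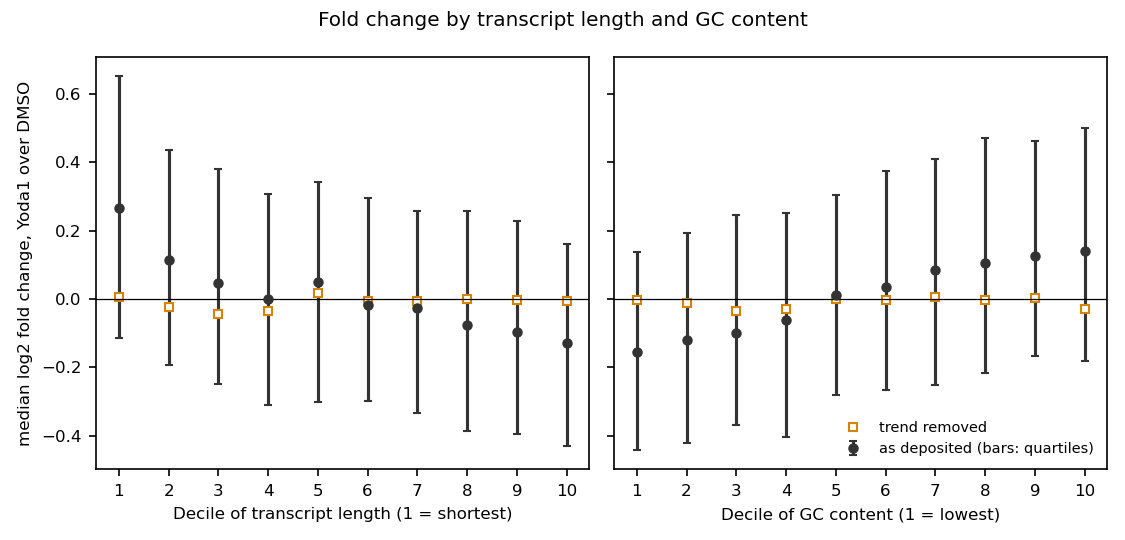
Median log2 fold change of Yoda1 over DMSO by decile of transcript length (left) and GC content (right), 963 or 964 genes per point. Filled circles with quartile bars are the deposited values, which run from 0.27 in the shortest to -0.13 in the longest decile, and open squares are medians with the trend removed.

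The authors' comparison stands on 3 libraries per group by the labels and the table's name, and the labels report a batch effect whose assignment to the kept libraries is not given in the sources used here. The spread between single libraries, the effect of any one of them and values within batches were not analysed here, and the part of batch in any difference above was not assessed.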

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

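The tests with a t distribution, against a fold of 0.5, with equal summed counts, median centring, the length and GC trend, plain symbols, ranks and a preset correlation of 0.05 were chosen after the data were seen. The count of 6518 genes past the threshold became 3977 with an absolute log2 fold change above 0.5 and 1486 above 1, where fewer genes meet both conditions. It became 2990 with a t distribution of 4 degrees of freedom and 1393 in the test against a fold of 0.5, both stricter by construction. Under the other alternatives it lay between 5851 and 6638. The number of lists called, 18, lay between 15 and 20, and of 31 tested genes among the largest changes and those fixed by name, 26 passed in the deposited comparison and 24 to 29 under the alternatives. Of the 37 lists, 28 kept their direction and side of the threshold under every alternative run, 5 lost a call and 2 gained one. The test of 2 uncalled lists turned: NF-kappaB genes with ranks (adjusted p = 0.50) and p53 targets with equal summed counts (0.996), and the cause was not tested. Of 163 named genes and list members, 130 kept their direction and side under every alternative, 27 lost a call in at least 1, 6 gained one and 0 changed sign. The 7 calls lost with the t distribution were those of Piezo1, Smad9, Ifit1, Ctsk, Rn7sk, Rpph1 and H1f2, and each was lost in the test against a fold of 0.5 too. Calls were gained by Smad6, Ccn1 and Pdpn with the length and GC trend removed, by Cebpa and Neat1 with equal summed counts, and by Tnfrsf11b with either.

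No paired analysis was possible because the deposited comparison holds no values per library. For that reason the intended analyses that leave out single replicates, add the excluded libraries, change the size factors, pseudocount or count test, use upper-quartile scaling, estimate the correlation between genes or use fry were not run, and neither were other splits of the samples. Precision at low levels limits the single genes, with a median standard error of 0.754 below a mean of 100.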

Other observations

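All gene groups and tests in this part were chosen after the data were seen, except for the collagen, ribosomal protein and BMP target lists. Of 7 tested keratin genes, which encode epithelial intermediate filaments, 5 were lower with Yoda1 (Krt14, Krt16, Krt9, Krt42 and Krt13) and 0 higher (camera adjusted p = 0.000222 over the added lists). Without Krt14 the median log2 fold change was -4.08 against -4.21 with it, at an adjusted p of 0.0572 (range over the alternatives 0.0282 to 0.265). In the authors' deposited table, Krt16 had a log2 fold change of -4.21 (standard error 0.39) and Krt9 one of -4.65 (0.54). Tetraspanin genes, which encode membrane scaffold proteins, went the other way, with 8 of 13 higher and Tspan18 lower (camera adjusted p = 3.41e-06, and 0.00834 without Tspan11). Besides Tspan11, the authors' deposited table gives log2 fold changes of 1.65 for Tspan4 (standard error 0.10) and 1.04 for Tspan17 (0.17). Of 20 genes for the COPI and COPII coats, which carry secretory cargo between the endoplasmic reticulum and the Golgi, 14 were lower and 0 higher (camera adjusted p = 1.14e-06), and the list stayed lower with the length and GC trend removed (9.89e-06). The COPII gene Sec23a was 2.47-fold lower (95% interval 2.06 to 2.95) and the COPI gene Arcn1 2.12-fold lower (1.84 to 2.45) in the authors' deposited table.

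The chromatin gene Hmga2 rose alongside its relative Hmga1, with a log2 fold change of 2.76 (standard error 0.07) in the authors' deposited table. Feedback regulators of MAP kinase signalling (dual-specificity phosphatases, Sprouty and Spred genes) had 8 higher and 5 lower members of 18 (camera adjusted p = 0.00113), a call that rested on members of the calcium and immediate-early list: without them 2 were higher (Spred1 and Spred2) and 5 lower of 11 (adjusted p = 0.953). Imprinted genes had 9 lower and 3 higher of 26 (camera adjusted p = 0.000282), among them Mest, Plagl1 and Grb10 with log2 fold changes of -3.90, -2.00 and -1.28 in the authors' deposited table. The 20 imprinted genes that had not been looked at before the list was drawn up gave no call as a list (camera adjusted p = 0.352). Of 85 nuclear-encoded respiratory chain subunits, 42 were higher and 13 lower (camera adjusted p = 0.000222). For 63 of the 85, too few for the length and GC check to stand for the group, a transcript length was found. Over those 63 the median log2 fold change went from 0.26 to 0.0096 with the trend removed, and the adjusted p from 0.00506 to 0.725. Mitochondrial ribosomal protein genes had 37 higher and 7 lower members of 78 (camera adjusted p = 0.00229), and proteasome subunits 19 higher and 3 lower of 38 (0.00834). A length was found for every tested member of both groups. Their calls were lost with the trend removed (0.189 for both) and with a preset correlation of 0.05 (0.0783 for both). With the trend removed, their medians went from 0.25 to 0.18 and from 0.21 to 0.079. The respiratory chain, mitochondrial ribosomal and proteasome genes were not left out of the trend fit, so a rise they share may have helped to make the trend. The loss of their calls on its removal therefore cannot tell whether length and GC explain their rise.

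The first pattern is the fall of collagens with a rise of ribosomal protein genes, long against short transcripts. With the trend of fold change on length and GC removed, the collagen median was -1.11 (quartiles -1.33 to -0.62) against -1.08 before (camera adjusted p = 1.83e-24). The fall of the list did not shrink. However, the fitted trend was small beside it, with medians of the length deciles from 0.27 to -0.13 only. Its removal could thus hardly have ended the call, so this outcome is weak evidence on the cause. Effects of length or GC of another form were not tested. The ribosomal protein median went from 0.31 (quartiles 0.06 to 0.74) to 0.052 (quartiles -0.13 to 0.49), and its call ended because the fold shrank while the spread stayed similar. Only members of the fixed lists were left out of the fit. Mitochondrial ribosomal and respiratory chain genes, which also rose, stayed in it, as did any well-measured ribosomal protein genes outside the list. A rise shared with them may have helped to make the trend. The shrinkage therefore cannot tell whether length and GC explain the rise of that median. Single members differed from it: Rps27a, Rps13 and Rps19, which had the smallest adjusted p of the list, still passed the threshold with the trend removed. Whether that trend came from the libraries or from the treatment was not tested, and an effect of Yoda1 on collagen genes remains an open, untested explanation.

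The second pattern is a set of folds above 5 on the log2 scale at a mean of at least 10, seen in 25 genes past the threshold. Of these, 12 (48.0%) were pseudogenes, unnamed gene models or rows of a symbol that occurs more than once. Among 12379 other tested genes with a mean of at least 10, the share was 6.60% (two-sided Fisher's exact test, p = 1.70e-08). Division of reads between near-identical copies may produce part of these large folds, but this share does not measure it. The unnamed gene models were not all pseudogenes, and likeness of sequence was not measured. Genes were also not matched by mean in this test. In the authors' deposited table, 1 row of Nnt stood at -10.91 (standard error 1.20) and the other at 1.27 (0.15). Adding the group means of both rows, taken from the deposited values for groups of equal size, gives a log2 fold change of 0.53. The rows of Pik3r3 stood at -9.58 (1.22) and -0.21 (0.11), and their sum gives -0.44. Those of Nt5dc3 stood at -8.58 (1.23) and -0.0021 (0.10), and their sum gives -0.12. In neither of these pairs did the other row rise as it did for Nnt. Gm12671, a pseudogene, stood at 13.66 (1.19) in the authors' deposited table, a fitted value that is no bound. The other 13 genes have names of their own. They include Hmga1b, a related sequence of Hmga1 that may take part of its reads, and Alpl, Tnfrsf19 and Jam2, for which an effect of the treatment stays open and untested.

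The third pattern is the rise of Grem1 with the fall of Bmp4, which could go with lower BMP output in the treated cells. The 19 other tested BMP targets had a median log2 fold change of -0.28, 5 higher (Id2, Id1, Smad7, Hes1 and Id3) and 7 lower, and gave no call (camera adjusted p = 0.259). Members that move both ways leave this hypothesis undecided: lower, unchanged and higher BMP output cannot be told apart here. SMAD phosphorylation and protein levels were not analysed here.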
